A study of Mus musculus with 2 samples.

How the data were processed

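H3K9me3, trimethylation of lysine 9 of histone H3, was measured by chromatin immunoprecipitation and sequencing in midbrain dissected from mouse embryos of strain B6NCrl at 15.5 days. Per the labels, the 2 libraries are biological replicates of 1 group, pooled from 78 embryos (replicate 1) and 62 embryos (replicate 2) of both sexes, so p-values measured here describe these 2 pools. The group has no second tissue, stage or treatment beside it, and no test between groups was made.

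The authors deposited 4 lists of peaks in the narrowPeak format with coordinates of the mm10 build, per the file headers. Each replicate list was derived from the filtered alignment of that replicate and 1 further file, the pooled list from both filtered alignments and 2 further files, and the replicated list from the pooled list and the 2 replicate lists, per the file headers. The aligner, the peak caller, its thresholds and the reads per library are not given in the sources used here. The enrichment of a peak is a fold ratio over background as the authors' peak caller gave it. The p-value and q-value of a peak are on the −log10 scale in the deposited lists. A display score per peak is also deposited and was not used. All of these are the authors' own values for a peak, and they served here only to describe, rank or filter peaks within a list.

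Depth was recovered from the deposited values. In every list, enrichment and p-value together fitted a whole number of fragments n at the summit and a background b, with the enrichment equal to (n + 1) / (b + 1) and the p-value equal to the Poisson chance of more than n fragments given b, and n lay within 0.05 of a whole number for 100% of peaks. The depth of each list is therefore given as fragments at the summit. The total depth of a library remains unknown.

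Genes, exons and transcription start sites (TSS) were taken from GENCODE release M21 on mm10, and sequence from the mm10 reference. Coordinates are printed 1-based. The replicated list was the main set of peaks. Peaks on the 21 assembled chromosomes entered the tests, and peaks on unplaced contigs entered only the description of lists and of the strongest peaks. The promoter was the annotated start of the gene ± 1 kb. In the test of position within zinc finger genes, the TSS and the last exon were those of the transcript with the longest coding sequence, so that its promoter count differs from that of the gene list. Peak bases were assigned to 6 classes in the order promoter, coding exon, UTR, other exon, intron and intergenic. Domains were replicated peaks merged across gaps of up to 10 kb. A CpG island was a merged run of 200 bp windows with GC of at least 50% and an observed over expected CpG ratio of at least 0.6. Uniqueness was the share of 32-mers that occur once in the genome, counting both strands, and it stood in for mappability.

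Enrichment tests compared the observed count or share with rotations. The exceptions were the comparison with length-matched gene lists and the CpG island test, which used random draws instead. In each rotation all peaks of a chromosome were shifted together by 1 random distance, with assembly gaps removed and the end joined to the start, so that widths, spacing and clustering of peaks and genes stayed as they were. There were 10000 rotations for gene lists and for position within zinc finger genes, 1000 for the annotation classes and the overlap of replicates, and 100 for base composition. These are two-sided permutation tests. The smallest p they can give is 0.0002, 0.002 and 0.02, in the same order. P-values were adjusted by the Benjamini-Hochberg method over the 21 lists, the 6 classes or the measures of a test, and a result was called at an adjusted p under 0.05. Ranges of rotations are 95% ranges. Rotations ignore mappability. The X/autosome comparison, the exons of the protocadherin cluster, CpG islands, uniqueness, peaks ranked by p-value and the gene families of the closing section were examined only after the data had been seen.

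A gene counted as marked when at least 1 bp of a peak lay over its annotated body. The 21 lists were KRAB/C2H2 zinc finger, olfactory receptor, vomeronasal receptor, clustered protocadherin, Hox, keratin, canonical histone, Rhox, Cyp2 and Ugt, interferon and Ifi200, defensin, serpin, imprinted, germline, midbrain and neuronal, housekeeping, hepatocyte, skeletal and heart muscle, blood cell, vascular and meningeal, and H3K9 methylation machinery genes. Families were selected by gene symbol, so that a few unrelated genes with a matching symbol can be included, and the other lists were written from textbook knowledge. Of the named members, 34 of 35 housekeeping, 23 of 24 hepatocyte and 28 of 29 machinery genes were found in the annotation, and all members of the other lists were. The genes named in the text were protein-coding genes with a replicated peak and a peak in both replicate lists: the 12 with the highest enrichment, the 12 with most bases under peaks, the 3 with the highest enrichment in each list (all, where a list had 5 or fewer), and the genes at the 5 strongest peaks and the 5 largest domains. Genes named outside this rule were chosen after their values were seen. Among them are Peg3, Usp29, Igf2r, Airn, Sycp1, Fkbp6 and the imprinted genes without a replicated peak, where the text does not repeat this. Groups, tests, lists, this rule and most alternatives were fixed before the data were examined.

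The list test was tested on simulated data with 1000 rotations, 2686 genes and 100 simulations. With no effect, 1.71% of list tests had a p under 0.05 and 1% of simulations had any list called. The simulated peaks were themselves rotations of the replicated list. This rate therefore holds under the rotation model only and does not cover departures from it such as mappability. With peaks added to 25% of the zinc finger list it was called in 100% of simulations, and with peaks added to 25% of the imprinted list that list was called in 68%. The alternatives tried were each replicate list alone (leaving out the other replicate), the pooled list, a stricter threshold (−log10 q of at least 2), other overlaps (50% of the peak, 50% reciprocal, at least 500 bp), other gene regions (5 kb flanks, promoter only, promoter of ± 2.5 kb), other null models (peaks shifted by 0.2 to 2 Mb, 10000 length-matched gene lists), autosomes only, zinc finger genes with a TSS more than 5 kb from the last exon, and merging gaps of 3 and 50 kb. Restricting the replicated list to peaks overlapped in both replicates or to peaks with at least 50% unique 32-mers was added after seeing the data. Reads, signal tracks and repeat families were not analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.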

Results

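H3K9me3, a histone mark of silenced chromatin, was mapped in the midbrain of mouse embryos at 15.5 days, in 2 biological replicates pooled from 78 and 62 embryos. The list of replicate 1 held 53400 peaks over 13.9 Mb and that of replicate 2 held 46953 peaks over 12.7 Mb, contigs included. Their peaks on the assembled chromosomes covered 0.516% and 0.472% of the sequence of those chromosomes without gaps. Peaks were narrow, with a median width of 213 bp in replicate 1 and 222 bp in replicate 2. The depth behind a peak was low: the median summit held 8 fragments in replicate 1, 10 in replicate 2 and 14 in the pooled list of 63102 peaks. Only 10.03% of peaks in replicate 1 and 13.9% in replicate 2 reached a deposited −log10 q of 2. The list the authors labelled replicated held 15793 peaks over 8.25 Mb, with a median width of 427 bp, a median enrichment of 3.44 and a median of 18 fragments at the summit, and 80.9% of its peaks reached a −log10 q of 2.

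The first question was whether both pools of embryos carried the mark at the same places. The named loci were chosen for their replicated peaks, so only the extent of coverage is compared there. Peaks covered 24.2% of the clustered protocadherin locus of chromosome 18 in replicate 1 and 24.0% in replicate 2. They covered 26.4% and 24.1% of Zfp936, a zinc finger gene of chromosome 7, and 83.1% and 95.6% of Klf14, a single-exon transcription factor gene of chromosome 6. Genome-wide, 13812 peaks of replicate 1 (25.9%) and 13735 of replicate 2 (29.3%) overlapped a peak of the other replicate by at least 1 bp. Rotated peaks of replicate 2 did so for 1.32% on average, a ratio of 21.8 (rotation permutation test, p = 0.002, the smallest 1000 rotations can give). Most peaks of either list therefore had no partner in the other, and the share with one depended on rank. In the decile of peaks with the smallest p-values 60.5% of replicate 1 and 63.5% of replicate 2 were matched, against 13.1% and 16.3% in the decile with the largest. With 50% of the peak covered, the matched share was 17.7% in replicate 1 and 19.8% in replicate 2, and with 50% reciprocal overlap 12.5% and 14.2%, at ratios over rotations of 29.9 and 31.1. Among peaks with a −log10 q of at least 2, the ratio for an overlap of at least 1 bp was 84.8, with 30.3% and 24.9% of the peaks matched.

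**Figure D1:**
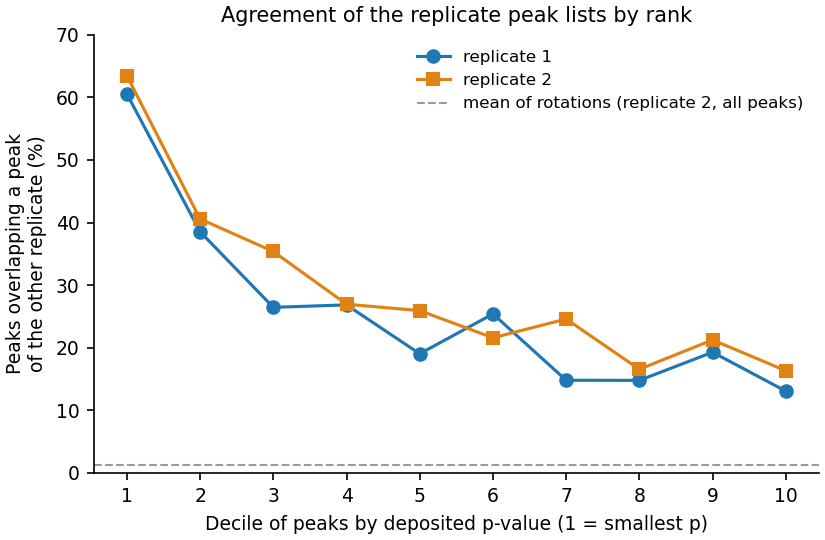
The x axis gives deciles of each replicate's peaks ranked by the deposited p-value, and the y axis the percent that overlapped a peak of the other replicate; the dashed line is the mean of rotations for replicate 2. The share was 60.5% and 63.5% in the first decile and 13.1% and 16.3% in the last, above the 1.32% of rotations throughout.

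The replicated list was drawn from the pooled one: all of its 15793 peaks were found in the pooled list, 25.03% of which they make up. They were wider than the pooled peaks left out (median 427 bp against 215 bp) and had a higher median −log10 q (3.22 against 1.34). All 12643 pooled peaks that shared at least 50% of either peak with a peak of each replicate were in the list, and they made up 80.1% of it. The remaining peaks met a rule that the deposited lists do not show. All comparisons that follow rest on the replicated list unless another list is named.

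Relative to rotations, the mark was more frequent over exons and less frequent over introns, although introns held more of its bases. Coding exons held 3.84% of peak bases, 2.64 times the mean of rotations. The longest coding exon of each of 18 gamma protocadherin genes was covered by 86.2% on average. The classes were not tested again without the protocadherin and zinc finger genes, so how much of the exon and promoter excess these supply is not known. The ratio for coding exons was lower in the lists of replicate 1 (1.67) and replicate 2 (1.82) and in the pooled list (1.75), with the call kept in each. UTRs held 2.43% (1.60 times) and other exons 3.16% (1.53 times). Introns held 28.5%, or 0.670 times the mean of rotations, and intergenic sequence 59.4%, or 1.18 times. The rotation permutation test gave an adjusted p of 0.003 for coding exons, UTRs, other exons and introns and 0.012 for intergenic sequence. Promoters of protein-coding genes held 2.64% of bases, 1.43 times the mean of rotations (permutation test, adjusted p = 0.026), but this call was lost when only peak centres were counted (adjusted p = 0.148), in the pooled list (ratio 1.08) and in the lists of replicate 1 (1.02) and replicate 2 (1.08). Peak sequence had a higher GC content than rotations (43.4% against 42.1%, permutation test, adjusted p = 0.030) and a lower ratio of observed to expected CpG (0.160 against 0.192, adjusted p = 0.030). The soft-masked repeat share, 32.6% in peaks and 34.1% in rotations, did not pass (permutation test, p = 0.158 over 100 rotations). Over all peak sequence, 90.4% of 32-mers occurred once in the genome, against 81.4% in 1 rotation, and 0.879% occurred at least 100 times, against 7.44%. The median peak was less unique than the median rotated peak, with 94.9% against 99.3% of 32-mers unique.

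Chromosomes 7, 17 and 4 carried most of the mark for their length. Chromosome 7 had 12.2 kb of replicated peak per Mb, 4.03 times the genome mean of 3.02 kb per Mb, chromosome 17 had 8.47 kb and chromosome 4 had 6.14 kb. In the replicates' own lists the values were 14.3 ± 0.999 kb per Mb for chromosome 7, 10.8 ± 0.583 for chromosome 17 and 7.64 ± 0.380 for chromosome 4 (mean ± SD, n = 2). Over all chromosomes, 28.0% of 15515 peaks lay within 100 kb of a zinc finger, vomeronasal receptor or clustered protocadherin gene. The share was 66.0% of the 1540 peaks on chromosome 17, 65.5% of the 615 on chromosome 18, 49.4% of the 3207 on chromosome 7 and 19.4% of the 1708 on chromosome 4, with no allowance for how many such genes each chromosome holds. The X chromosome had 0.804 kb per Mb, 0.266 times the mean, and the Y chromosome 0.0597 kb per Mb with 12 peaks. These densities make no allowance for the copy number of the sex chromosomes in pools of both sexes, or for mappability. The order 7, 17, 4 held in the replicated, pooled and both replicate lists and at the stricter threshold, and 19 of 21 chromosomes stayed on 1 side of the mean in all 5. Relative to the mean, the X chromosome rose from 0.266 to 0.520 in the pooled list, 0.559 in replicate 2 and 0.877 in replicate 1. No test between chromosomes was made.

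**Figure D2:**
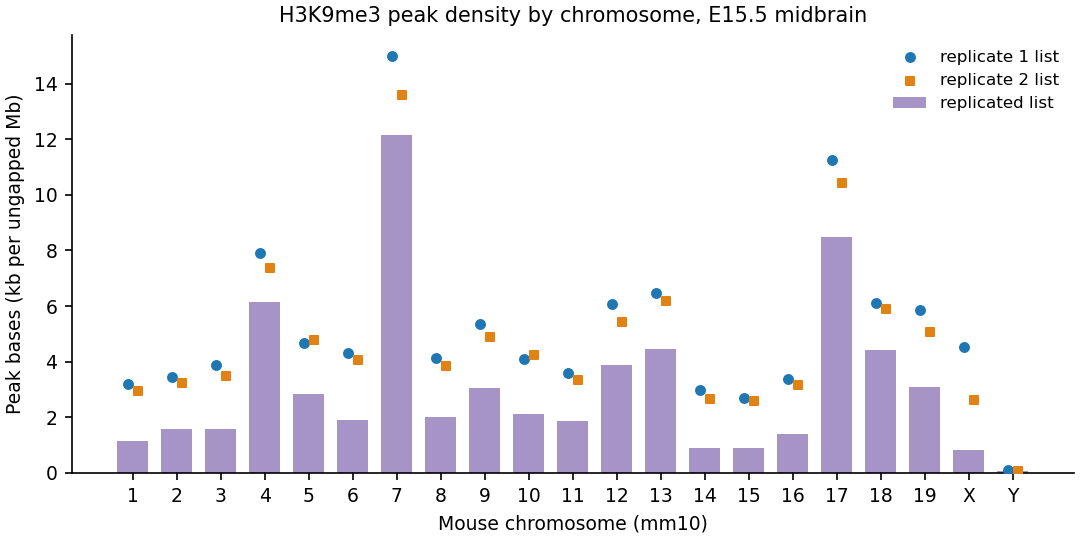
Bars give kb of replicated peak per Mb of ungapped sequence (y axis) for each mouse chromosome (x axis), and points give each replicate's own, longer list. Chromosome 7 stands at 12.2 kb per Mb, chromosome 17 at 8.47 and chromosome 4 at 6.14, and the replicates lie furthest apart on the X chromosome, at 4.53 and 2.64, and on chromosome 7, at 15.01 and 13.6.

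Merging peaks across gaps of up to 10 kb gave 5426 domains, of which the 532 with at least 5 peaks held 65.9% of all peak bases. The largest, on chromosome 7 from 17883304 to 18188112, held 166 peaks and 104.7 kb of peak over Ceacam11, Ceacam12 and Ceacam13, cell adhesion genes, with Igfl3 and Gm5155. The second spanned 121.9 kb of the gamma protocadherin cluster on chromosome 18 (37655769 to 37777691), and peaks covered 70.5% of it in the replicated list, 57.1% in replicate 1 and 55.3% in replicate 2. The third, on chromosome 7 from 11660831 to 12018078, covered the pheromone receptor genes Vmn1r72 to Vmn1r76, and the fourth lay over Gm12887 on chromosome 4 (121476012 to 121726805). The fifth covered the alpha protocadherins (chromosome 18, 36897517 to 37079677). Outside the protocadherins, the protein-coding gene with most bases under peaks was Skint5, of a family of epithelial immune genes, with 148 peaks and 71056 bp (chromosome 4, 113477891 to 113999503). The rank of a domain depended on the list and the gap: the largest was the gamma protocadherin domain with a 3 kb gap, a protocadherin domain in replicate 2, a domain on chromosome 17 with a 50 kb gap and in the pooled list, and another on chromosome 7 in replicate 1. The stricter threshold left the Ceacam domain first. The number of domains moved too, to 245 domains of at least 5 peaks with a 50 kb gap, 1105 in the pooled list, 864 in replicate 2 and 910 in replicate 1.

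A peak of 2943 bp on chromosome 6 (30956227 to 30959169) covered 93.3% of Klf14 with an enrichment of 9.19 and was the strongest over any protein-coding gene. Of the 5 strongest peaks, 3 lay on 1 unplaced contig with no annotated gene (enrichment 11.5, 11.1 and 8.49), and 1 on the Y chromosome (259022 to 259544, 8.999), 51233 bp from Gm29277. Gm21411 on chromosome 4 followed among genes with 7.48. Peaks over the gamma protocadherins Pcdhga1 to Pcdhga7 shared a maximum of 7.12, set by 1 peak (37733166 to 37735018) that also lies inside the annotated spans of Pcdhgb1, Pcdhgb2 and the readthrough genes Gm42416, Gm37013 and Gm37388.

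Zinc finger, vomeronasal receptor, clustered protocadherin and imprinted genes carried the mark more often than rotations gave. Of 21911 protein-coding genes, 1614 (7.37%) had a replicated peak over the body. The share was 126 of 427 zinc finger genes (29.5%), 90 of 328 vomeronasal receptor genes (27.4%), 51 of 56 clustered protocadherin genes (91.1%) and 24 of 45 imprinted genes (53.3%). The other 17 of the 21 lists were not called. Against rotations the ratios were 3.48 for zinc finger genes, 3.87 for vomeronasal receptors and 4.67 for imprinted genes (adjusted p = 0.0014 each, rotation permutation test), and 5.60 for protocadherins (adjusted p = 0.0021). All 4 were also called in each replicate's own list, at lower ratios of 1.72 and 1.76 for zinc finger genes, 2.30 and 1.99 for vomeronasal receptors, 2.00 and 2.10 for protocadherins and 2.24 and 2.18 for imprinted genes in replicates 1 and 2. When peaks were shifted only by 0.2 to 2 Mb, within the same neighbourhood, the ratio of zinc finger genes fell to 1.69 (126 genes against 74.4) with the call kept, and that of vomeronasal receptors fell to 1.36 with the call lost.

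**Figure D3:**
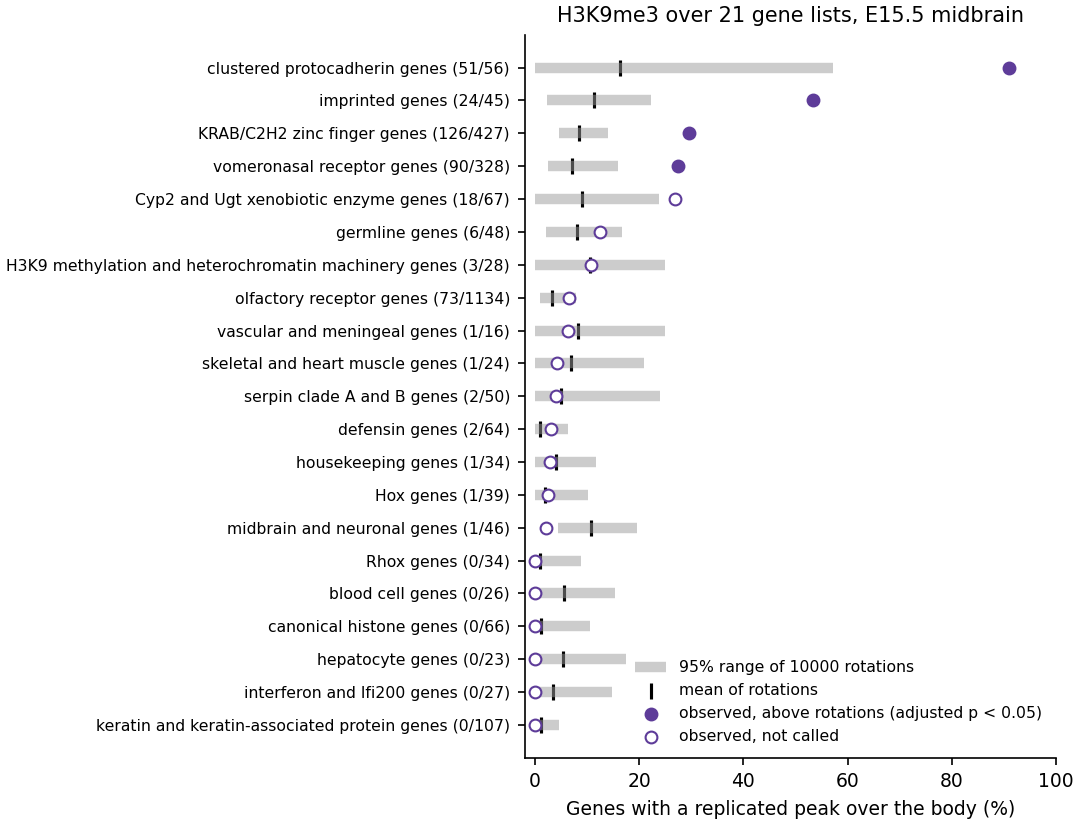
The x axis gives the percent of genes of each of 21 lists with a replicated peak over the body (circles, filled where called), with the mean (tick) and 95% range (grey bar) of 10000 rotations. Protocadherin (91.1%), imprinted (53.3%), zinc finger (29.5%) and vomeronasal receptor genes (27.4%) lie above the range and were called.

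Zinc finger genes, many of which encode repressors that recruit H3K9 methylation to transposons, carried the mark over the last exon far more often than over the promoter. A peak lay over the last exon, which in many of these genes encodes the array of fingers, in 95 of 427 genes, against 9.73 in rotations (95% range 2 to 24, ratio 9.77). It lay over the promoter in 11, against 8.69 in rotations (range 1 to 21). The difference of 84 genes compared with a range of −6 to 8 in rotations (rotation permutation test, adjusted p = 0.0003). The promoter count did not pass the same permutation test (p = 0.613). A peak lay over the last exon and not the promoter in 87 genes, over both in 8 and over the promoter and not the last exon in 3; the rest of the gene was not part of this comparison. In the list of replicate 1 the last exon was marked in 124 genes, against 23.8 in rotations, and in that of replicate 2 in 119, against 21.8, so that the ratio fell to 5.21 and 5.45. The promoter counts were 14 and 15, against 20.6 and 18.9. Of the 3 zinc finger genes with the highest enrichment, Zfp936 (chromosome 7, 43114229 to 43192109) had 40 peaks reaching 7.07 over 29.2% of its body. Zfp81 (chromosome 17, 33329342 to 33358878) had 13 peaks reaching 6.87, and Zfp982 (chromosome 4, 147492417 to 147513486) had 9 reaching 6.75. When only the start of the annotated gene counted, 7 of 427 were marked, a ratio of 0.792, and the list was no longer called.

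**Figure D4:**
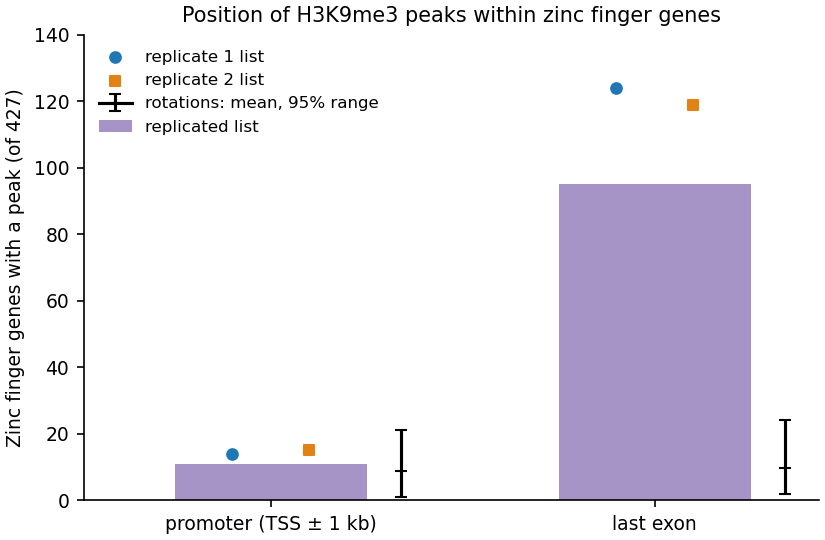
The y axis counts zinc finger genes, of 427, with a peak over the promoter or over the last exon; bars show the replicated list, points each replicate's list, and black lines the mean and 95% range of rotations. The last exon was marked in 95 genes and the promoter in 11.

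The clustered protocadherins, cell-surface proteins that give neurons distinct identities, were marked over nearly every variable exon. Over 911.7 kb of chromosome 18 (36930184 to 37841873) lay 345 replicated peaks, 56.1% of those on the chromosome, with a median of 20 fragments at the summit. Because all genes of the alpha and gamma groups share their last exons, a gene body can be marked by a neighbour's exon, and the exons were examined one by one, a step chosen after the data had been seen. The longest coding exon of each gene was covered by 86.2% ± 14.4 in the gamma group (SD over 18 exons), 70.3% ± 11.6 in the alpha group (11 exons) and 51.8% ± 23.9 in the beta group (22 exons, 20 with a peak). In the replicates' own lists these means were 68.2% and 72.1% for gamma, 59.1% and 54.7% for alpha and 39.2% and 40.2% for beta. The C-type genes Pcdhac1, Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5 had no replicated peak base over that exon, nor did the 6 constant exons. The lists of the replicates put a mean of 0% and 1.77% of the C-type exons under peaks. Counting promoters only, 49 of 56 genes were marked, 71.4 times the mean of rotations. The promoter window of ± 1 kb can reach into the longest coding exon: Pcdhga1 starts at 37661793 and that exon at 37661945. The promoter count is therefore not separate from the exon result. Pcdhga1 (37661793 to 37841873) had 73 peaks over 45.8% of its span, and Pcdha1 (36930184 to 37187661) had 85 over 23.3%.

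**Figure D5:**
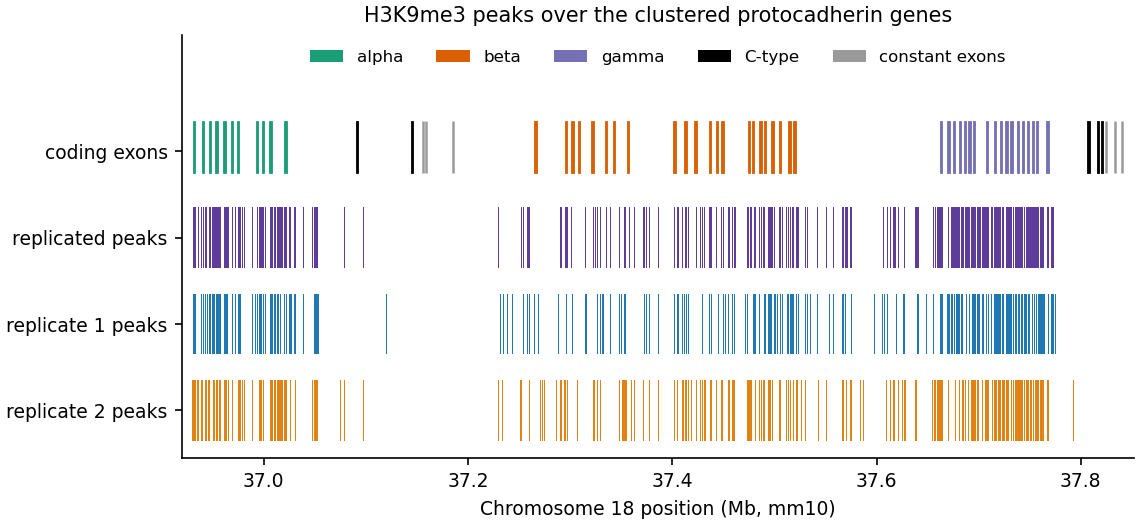
Map of the clustered protocadherin locus on chromosome 18 (x axis, position in Mb on mm10) with the longest coding exon of each gene by group and the constant exons above the peaks of the replicated list and of each replicate. Replicated peaks overlie 49 of the 56 exons, and none of the 5 C-type exons or the 6 constant exons.

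The marked genes of the imprinted list, which are expressed from 1 parental copy, carried peaks of moderate enrichment. The peaks numbered from 1 over Mest to 5 over Gnas and Grb10 and 7 over Snrpn. The list was written from textbook knowledge and can leave out imprinted genes. The 24 marked genes shared 18 distinct strongest peaks, because neighbours overlap: 1 peak served Peg3 and Usp29 (chromosome 7, 6730204 to 6730789, enrichment 4.12, at both starts), 1 served Igf2r and its antisense transcript Airn (chromosome 17, 12742403 to 12743044, 3.396), and 1 served Nap1l5 and its host gene Herc3 (chromosome 6, 58906373 to 58907318, 4.31). The highest enrichment within the list was 4.38 in Gnas (chromosome 2, 174299273 to 174300140), which encodes a G protein subunit. Nespas, Nnat, Mest, Snrpn, Impact, Plagl1, Grb10, Kcnq1ot1, Inpp5f and Peg13 were also marked, with values of 3.64 to 4.16, chosen after their values were seen. No replicated peak was called at this depth over the annotated bodies of H19, Igf2, Cdkn1c, Dlk1, Meg3, Peg10, Ndn or Rasgrf1. Sequence beyond the bodies was not examined gene by gene, so a peak near these genes is not excluded. Of these, Peg10 had peaks in the lists of both replicates (8.51% and 5.07% of its body), as did Rasgrf1 (0.325% and 0.402%), while H19, Igf2 and Dlk1 had none in either. At promoters 9 of 45 were marked, a ratio of 9.80 (permutation test, adjusted p = 0.0042).

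Vomeronasal receptor genes, which encode pheromone receptors, included Vmn2r10 (chromosome 5, enrichment 5.86), Vmn1r60 and Vmn1r71 (chromosome 7, 5.26 each), and peaks covered 30.99% of Vmn1r71. The loss of their call under shifts of 0.2 to 2 Mb came with a ratio of 1.36 (permutation test, adjusted p = 0.117). Olfactory receptor genes were marked in 73 of 1134 cases, 1.99 times the mean of rotations, and did not pass the permutation test (adjusted p = 0.436), although they did against length-matched lists of genes (ratio 1.90, adjusted p = 0.0007). Olfr357 (6.27), Olfr346 (5.05) and Olfr398 (4.87) had the highest enrichment. Cyp2 and Ugt genes, which encode enzymes of drug and steroid metabolism, were marked in 18 of 67 cases, 2.998 times the mean of rotations (permutation test, adjusted p = 0.128), led by Cyp2b9 and Cyp2c39 (5.05 each) and Cyp2c29 (4.85). That list was called in the pooled list (ratio 1.84), with at least 500 bp under peaks (5.05) and against length-matched lists (4.16).

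Germline genes, many of which are silent in somatic tissue, were marked in 6 of 48 cases, against 3.88 in rotations (permutation test, ratio 1.55, adjusted p = 0.863). Dazl, Ddx4, Sycp1, Taf7l and Fkbp6 were marked at the promoter, and Piwil1 within the body. With promoters only, these 5 of 48 were 9.78 times the mean of rotations (permutation test, adjusted p = 0.0042). Dazl, an RNA-binding protein of germ cells, had the strongest of these peaks (chromosome 17, 50293465 to 50293855, enrichment 5.04, 27 fragments), followed by Taf7l on the X chromosome (3.84) and Ddx4 on chromosome 13 (3.37). The peak of Fkbp6 had no counterpart over the gene in replicate 2, nor that of Sycp1 in replicate 1.

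Of 46 midbrain and neuronal genes, 1 had a peak, against 4.94 in rotations (permutation test, ratio 0.202, p = 0.048, adjusted p = 0.169), which did not pass. It was Syt1, a synaptic vesicle protein, with 3 peaks over 0.262% of its body. In the list of each replicate 9 of 46 were marked, with ratios of 0.589 in replicate 1 and 0.617 in replicate 2, also not called. Markers of other cell types that a dissected midbrain could hold were marked in 1 of 16 vascular and meningeal genes and 0 of 26 blood cell genes, and those of tissues outside it in 1 of 24 muscle genes (Ttn, 5.29) and 0 of 23 hepatocyte genes. Housekeeping genes were marked in 1 of 34 cases (Tbp, 3.44) and Hox genes in 1 of 39 (Hoxc5, 3.03). Hox genes were marked in 5 of 39 cases in replicate 1, 9 in replicate 2 (ratio 2.93) and 11 in the pooled list (ratio 3.17), without a call in any. The machinery of H3K9 methylation was marked in 3 of 28 genes, among them Atf7ip (4.04) and Smchd1 (3.23), against 2.95 in rotations, but in the pooled list in 4 of 28 against 11.01, a ratio of 0.363 (permutation test, adjusted p = 0.0175). Among other clusters, 2 of 64 defensin genes (Defb33, 4.04; Defb7, 3.03) and 2 of 50 serpin genes (Serpinb9e, 3.39; Serpinb6d, 3.29) were marked, and none of 107 keratin, 66 canonical histone, 34 Rhox and 27 interferon and Ifi200 genes. The lists with no marked gene had few in rotations too. Their means were 1.47 blood cell, 1.23 hepatocyte, 1.15 keratin, 0.745 canonical histone, 0.304 Rhox, and 0.924 interferon and Ifi200 genes. None of the lists in this paragraph passed the test on the replicated list.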

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

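All alternatives were planned except the 2 that restrict the replicated list to peaks overlapped in both replicates or to mostly unique sequence. These 2 were chosen after seeing the data and changed no call. The uniqueness filter kept 15238 of 15515 peaks, so it could change little, and the rotations still ignored mappability. Of 360 comparisons of a main result with an alternative, 325 kept direction and side of the threshold or moved within a set limit. Of the others, 4 lost a call, 5 gained one, 2 turned direction and 24 values moved beyond that limit. For counts of domains and of called lists the limit was a fixed factor. For other values without a test it was the SD of the values from the 2 replicate lists. Those lists are among the alternatives themselves, so this SD does not measure the variation of the replicated list. Direction was compared only where a call was made under the main or the alternative setting. The promoter share of peak bases (main ratio 1.43) lost its call in the pooled list (1.08) and without a replicate (1.02 to 1.08). Counting promoters only put the zinc finger list under the mean of rotations with no call (0.792) and gained germline genes (9.78). Local shifts ended the vomeronasal call (1.36). Length-matched lists, which ignore clustering, gained olfactory receptors (1.90) and Cyp2 and Ugt genes (4.16); the latter were also called in the pooled list (1.84) and with at least 500 bp (5.05). The pooled list put the machinery genes under rotations, with a call (0.363). Density over the genome mean on chromosome 7 (main 4.03) was 2.88 to 2.91 without a replicate, 3.21 pooled and 4.08 at the stricter threshold; on chromosome 17 (2.80) it was 2.18 to 2.21, 2.33 and 2.85, and on chromosome 4 (2.03) 1.53 to 1.56, 1.59 and 2.12. On the X chromosome (0.266) it was 0.559 to 0.877 without a replicate and 0.520 pooled. Domains of at least 5 peaks numbered 532, then 245 with 50 kb gaps, 864 to 910 without a replicate and 1105 pooled, with 65.9% of peak bases in them, then 42.6% with 3 kb gaps, 74.97% with 50 kb gaps, 47.9% to 49.2% without a replicate and 56.8% pooled. In all of these the cause was not tested. Of 180 comparisons over the 45 named genes, 121 moved, and 3 genes had no peak base left at the stricter threshold. No paired analysis was possible because there is only 1 group. Depth limits all of this: with a median of 8 and 10 fragments at the summit per replicate, the absence of a peak is not the absence of the mark.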

Other observations

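The tests of a looser threshold on the X chromosome and of less unique zinc finger exons were chosen only after the result was seen, as were the gene families and single genes named here, while those of longer targets for zinc finger genes and of gene length for imprinted genes used planned comparisons that were turned into tests of these explanations after the result was seen.

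Several gene families outside the fixed lists were marked more often than rotations gave. Of 9 placental cathepsin genes of chromosome 13, proteases of the placenta, 8 carried a replicated peak, against 0.266 in rotations (95% range 0 to 2), and 8 did in each replicate's list. The promoters of Ctsr (4.85), Cts6 (4.32), Cts3 (4.24), Cts7 (4.07) and Ctsj (4.04) were among those with a peak. Of 11 Skint genes, 9 were marked, against 2.12 (range 0 to 7), with 11 in replicate 1 and 10 in replicate 2. Ceacam genes were marked in 7 of 15 cases, against 1.44 (range 0 to 6), and Pramef, Pramel and Oog genes, of germ cells and oocytes, in 6 of 16, against 0.545 (range 0 to 5). These families were picked because they had peaks, so no p-value is given.

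Of 311 protein-coding promoters with a replicated peak, 274 also had a peak in both replicate lists. Protocadherin genes made up 48 of them, vomeronasal receptors 37, olfactory receptors 32, imprinted genes 7, zinc finger genes 5 and germline genes 3, and 136 belonged to no list. Midbrain, neuronal and housekeeping genes made up 0. Rotations of the replicated list marked a mean of only 0.49 promoters in the midbrain and neuronal list and 0.45 in the housekeeping list. The protocadherin promoter windows can reach into the longest coding exon, as described above. The unlisted promoters with the highest enrichment were Klf14 (9.19, chromosome 6), Tcfl5 (6.47, chromosome 2), Gm37388 (6.06) and Gm37013 (5.64), which start among the alpha protocadherins, Rbmxl2 (5.26, chromosome 7) and Slc25a2 (4.93), which lies between the beta and gamma protocadherins.

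Ranking by p-value picked other places than ranking by enrichment. The 25 peaks with the smallest p had a median background of 127 fragments, 32.2 times that of the list, and a median enrichment of 3.37, against 3.44 in the list. Of these 25 peaks, 24 had a background over 5 times the median of the list. Across the replicated list 263 peaks did, and they were not filtered out. Of the 25, 8 lay on contigs and 1 was also among the 25 with the highest enrichment. Their neighbours included Sfi1 and Drg1 on chromosome 11 (3184208 to 3200097).

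Replicate 1 had more peak bases than replicate 2 on the X chromosome, by a ratio of 1.72, above the autosomes, which ranged from 0.972 to 1.16. A looser threshold on all chromosomes would place the X chromosome among the autosomes only if the peaks of both were equally weak. In replicate 1 the X peaks were weaker, with a median −log10 q of 0.441 against 0.846 on autosomes. In replicate 2 both medians were 0.754. The X ratio therefore cannot decide on a looser threshold. A few X regions that gained the mark would hold most of the excess. The 2 largest of 18 bins of up to 10 Mb held 18.7% of it, which argues against such regions as the whole cause. A whole-chromosome difference in read dose, in the replicates or their backgrounds, could not be decided by the rule set beforehand. Of the 18 bins, 16 (88.9%) lay above the highest autosome, just short of the 90% required. The 2 bins from 160 Mb on, with ratios of 1.05 and 1.01, did not. The last of them is a short remainder (170000001 to 171031299) with only 6.368 and 6.325 kb of peak. Leaving it out would lift the share above 90%, but that choice would follow the result. The excess was in weak peaks, since 98 peaks of replicate 1 and 116 of replicate 2 reached a −log10 q of 2, and 7.64% of the X peaks of replicate 1 were matched in replicate 2, against 26.6% on autosomes. A different share of male and female embryos in the pools, which the labels leave open, is a possible explanation that was not tested.

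Peaks over the last exons of zinc finger genes could come from reads shared between near-identical exons or from the exon being a longer target than the promoter. Of 296 last exons with at least 90% unique 32-mers, 60 carried a peak, against 6.63 in rotations (95% range 1 to 17), which argues against shared reads as the cause in these. Among the other 131 exons 35 did, and their share of 26.7% against 20.3% did not pass Fisher's exact test (p = 0.165), so for these exons the part of shared reads stays open. The excess of 84 genes over the promoter count lay outside the rotations' range of −6 to 8, and rotations carry the same difference in length. That the fingers' coding sequence itself is what is marked remains a hypothesis.

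Imprinted genes may carry peaks at CpG islands rather than across their length. Length-matched random lists gave fewer marked genes by a factor of 6.14, which argues against gene length as the cause. Of their 18 distinct strongest peaks, 66.7% lay on a CpG island, against 10.4% of the strongest peaks over 1532 other peak-bearing loci (permutation test, p = 0.0002, the smallest 10000 draws can give). This was predicted before it was measured and is consistent with peaks at the islands that control imprinting, a hypothesis, since no annotation of those control regions was used here and the parental copies cannot be told apart.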
